A study of Drosophila melanogaster with 3 samples.

How the data were processed

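ChIP-seq was performed, per the labels, on sonicated chromatin of whole embryos aged 0 to 24 hours from flies that express CG6791 fused to eGFP, with an antibody against GFP and fragments of 200 to 800 bp. The 3 libraries were grouped as 3 replicates of 1 group, with the replicate number taken from the labels, which call them biological replicates and register a separate biosample for each. All come from one fly line. A control experiment is named in the labels but was not analysed here.

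For each replicate the authors deposited a ranked list of candidate peaks and a thresholded list, and for the whole series 4 ranked and 4 thresholded lists, one of them called conservative. Per the descriptions deposited with the files, the lists are in dm6 coordinates, and the series lists derive from the alignments of all 3 replicates together with further files that are not described. The irreproducible discovery rate (IDR) method compares the ranks of peaks between 2 sets of calls. The aligner, the peak caller and their versions are not given in the sources used here. The deposited lists give each peak a score, capped at 1000, that rises as the IDR falls. They also give a signal value, the authors' measure of the enrichment of the peak, whose exact definition is not given in the sources used here. The ranked lists give the −log10 of the IDR, per the layout of the deposited files. The lowest score in the thresholded lists was 830, at which the −log10 column of the ranked lists gave an IDR of 0.01. Signal values were not scaled between replicates, and served to rank and describe peaks within a list. Across lists they entered rank correlations, and the mean ± SD and coefficient of variation of a site's signal over the 3 own lists, which include any difference in scale between the lists and were not tested. The 8 columns of the series' ranked lists that hold values of single libraries carry no sample name and were not used.

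Which pair of replicates a series list compared by IDR is not given in the sources used here, and was inferred from exact matches between its recorded intervals and those of the replicates' own ranked lists. The conservative list matched replicates 1 and 3 (81.1% and 69.4% of intervals), and the others matched replicates 1 and 2, replicates 2 and 3, and neither pair, the last being called pooled here. A list is named after the pair it matched, which does not mean that its signal values came from that pair alone. Signal values were equal at 100% of the intervals that any pair of the series' ranked lists shared. Over the 1916 conservative peaks held by all 3 replicates, the signal was a median of 0.985 times the sum of the strongest overlapping peak in each of the 3 own lists (quartiles 0.946 and 1.02), and 1.46 times the sum over replicates 1 and 3. All 4476 of its peaks were among the 4631 candidates at or above the score of 830, and the reason for the absence of the other 155 is not given in the sources used here. Candidates used as background were the ranked candidates behind the conservative list that scored below 830 and overlapped no thresholded list (137067).

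Overlap meant at least 1 bp. Chance overlap came from 100 seeded draws from each replicate's ranked list. Signal agreement was Spearman's rho over overlapping peaks. Gene models were Ensembl release 115 for the reference assembly, whose arm lengths hold every peak end, and the sequence was the RefSeq copy of the same assembly. Entries for transposable elements (5889) were not counted as genes, which left 18277 genes, 13968 of them protein-coding. A summit within 500 bp of any TSS was called a promoter summit. Other summits took the first of 5′ UTR, coding exon, 3′ UTR, non-coding exon, intron and intergenic DNA that applied. Motifs and 8-base words were counted as present or absent in 101 bp windows at the summit, against windows centred 500 bp to each side. Words were tested when present in at least 10 windows. Shares were compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment within each family, and intervals are 95% Wilson intervals. Windows, sites and genes are not independent replicates, so these p-values describe the lists, and the replicates' own lists carry the spread between libraries. Gene lists held 8 to 290 genes matched by symbol or gene type, and 1 listed symbol without a match was left out of each of 2 lists. No read counts were available, so no count model was used.

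The named genes were chosen by a rule fixed before the data were examined. It took the 15 strongest conservative peaks held by all 3 replicates by their nearest TSS, the 3 strongest members of each list past the threshold and the strongest member of each other list. It also took every bound member of the insulator and heterochromatin lists, CG6791 and w. The alternatives were fixed at the same time. They were other TSS windows (200 and 1000 bp), protein-coding TSSs alone, other backgrounds, a window of 100 bp each side, 7-base words, stricter overlaps, the replicates' own lists, the other series lists, the peaks above the median signal and leaving out each replicate. Counting transposable elements as genes, keeping the peaks held by all 3 replicates and comparing motifs of intron and intergenic sites over the same peak sets were added after seeing the data.

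The statistics were tested on data with known answers, made from deposited intervals, real flanks and simulated gene calls. A planted overlap of 60.6% was recovered as 60.8% of 4000 intervals. Among 29134 8-base words compared between left and right flanks, 0 were called, and a word planted in 223 windows ranked 1 of 29200. A list of 73 genes bound at 50% against 27% was called in 88% of 100 simulations, and lists without a difference in 0.278% of 1800 tests. These simulations drew each protein-coding gene on its own and left out the lists by gene type. They therefore do not cover lists whose genes share summits, such as the tRNA genes. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.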

Results

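Chromatin immunoprecipitation followed by sequencing (ChIP-seq) recovered DNA associated with CG6791 in whole Drosophila melanogaster embryos aged 0 to 24 hours. The flies carried CG6791, a gene known by its annotation number, as a fusion with enhanced green fluorescent protein (eGFP), and the fusion was precipitated with an antibody against GFP. The series held 1 group of 3 biological replicates, with no second condition and no control library among the libraries analysed. The comparisons were therefore made between replicates, and between called sites and candidate sites or flanking DNA within the same libraries. Read depth per library was unknown, because the files held peaks and not reads. All coordinates are dm6, and signal values are the authors' own value per peak, not scaled between lists, so values set side by side across lists are descriptions.

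CG6791-eGFP was found at 2643 to 3564 sites in each replicate, and the same sites recurred. Replicate 1 had 3564 peaks, replicate 2 had 2643 and replicate 3 had 2957, a mean of 3055 ± 468 (SD, n = 3). They covered 797 ± 174 kb (SD, n = 3) of the genome. Of the peaks of replicate 2, 79.0% overlapped a peak of replicate 1 and 79.4% a peak of replicate 3. Replicate 1, the longest list, had the lowest shares, at 59.6% with replicate 2 and 66.4% with replicate 3. Replicate 3 shared 78.6% of its peaks with replicate 1 and 70.7% with replicate 2. The mean over the 6 ordered pairs was 72.3% ± 8.17 (SD). Random draws of as many candidates from the replicate's own ranked list gave a mean of 2.59%, and none of 100 draws reached the observed mean (one-sided permutation p = 0.0099, the smallest that 100 draws can give). Draws matched on nearness to a TSS gave 10.8%. In replicate 1, 983 peaks (27.6%) overlapped neither other replicate, against 341 (12.9%) in replicate 2 and 419 (14.2%) in replicate 3.

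Among peaks that passed in both replicates of a pair, stronger sites in one tended to be stronger in the other. Across overlapping peaks, which are not independent replicates, Spearman's rho of the signal values was 0.702 between replicates 1 and 2, 0.779 between replicates 1 and 3 and 0.806 between replicates 2 and 3. Their mean was 0.762, and over the ranked candidates it fell to 0.277. The authors' conservative list held 4476 peaks. Its intervals matched replicates 1 and 3 as the pair compared by IDR, while its signal values were close to the sum over all 3 replicates. Of these peaks, 1916 (42.8%, 95% Wilson interval 41.4 to 44.3) overlapped a peak in all 3 replicates' own lists and 859 (19.2%, 18.1 to 20.4) overlapped none. The peaks held by all 3 replicates had a median signal of 282, against 85.2 for those held by none. Wilson intervals here cover counting error only. The share held by all 3 replicates fell to 31.5% when the overlap had to cover 50% of both peaks.

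The sites lay at gene starts. Of the conservative summits, 76.5% (75.2 to 77.7) were within 500 bp of an annotated transcription start site (TSS), against 13% of 137067 ranked candidates that passed no list (odds ratio 21.7, two-sided Fisher's exact test, p below the smallest double, 2.23e-308). In the replicates' own lists the share was 83.1% ± 2.47 (SD, n = 3). The 3422 promoter summits had a median distance of 45 bp to the nearest TSS (quartiles 22 and 85 bp). Introns held 10.9% of the summits, against 36.3% of the candidates, and intergenic DNA held 7.84%, against 22.7%. Coding exons held 2.59%, against 21.5% of the candidates. All 8 classes differed from the candidates (Fisher's exact test with Benjamini-Hochberg adjustment, highest adjusted p = 1.49e-04). The intron and intergenic shares were lower in the replicates' own lists, at 7.17% ± 1.72 and 6.46% ± 1.04 (SD, n = 3). Both classes together held 18.7% of the conservative summits, and 8.34% to 10.1% of the peaks shared by any pair of the replicates' own lists.

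**Figure D1:**
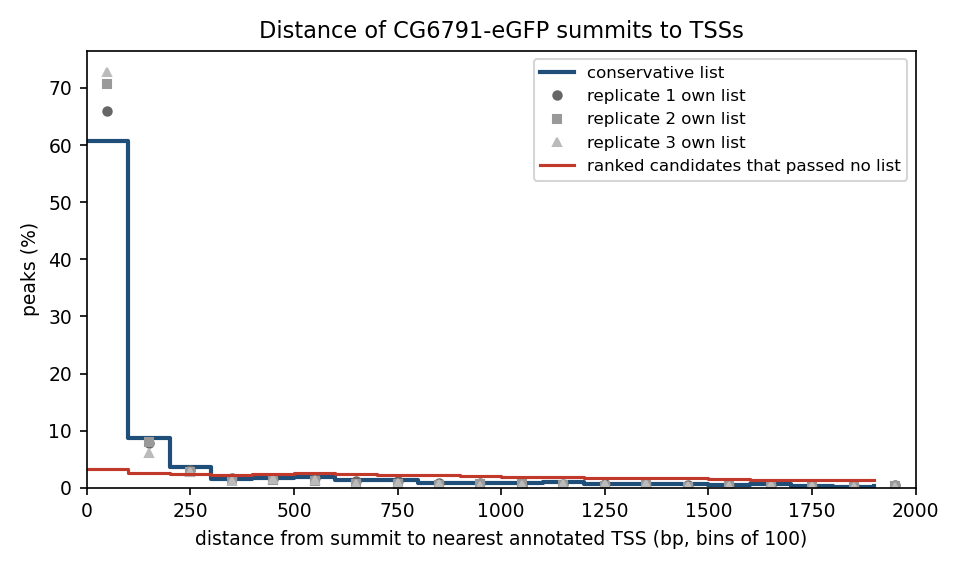
Distance from each summit to the nearest annotated TSS in bins of 100 bp (horizontal axis, bp) against the share of peaks (vertical axis, percent), for the conservative list (blue line), each replicate's own list (grey symbols) and ranked candidates that passed no list (red line). The conservative list and all 3 replicates peak in the first 100 bp, and the promoter summits had a median distance of 45 bp.

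Sites were spread over all major chromosome arms in shares close to those of the candidates, apart from the small chromosome 4 and the Y. Arms 2L, 2R, 3L, 3R and X held 18.2%, 21.0%, 19.9%, 22.6% and 17.4% of the conservative peaks. Chromosome 4, which is small and rich in repeats, held 35 peaks (0.782%), against 0.257% of the candidates (odds ratio 3.06, exact adjusted p = 1.57e-07). Chromosome Y held 1 peak (0.0223%), against 0.399% of the candidates (exact adjusted p = 2.47e-06), and unplaced scaffolds held 9 (0.201%, against 1.74%, adjusted p = 1.26e-21). Arms 2L and 2R held slightly more and 3R slightly less than the candidates (exact adjusted p = 0.0177, 0.0177 and 0.032, odds ratios 1.11, 1.10 and 0.922). Of the 155 passing candidates that the conservative list lacks, more lay on 3R than on any other arm. The shares were not recomputed with them. The call of 2L was lost in the own lists of replicates 1, 2 and 3 (exact adjusted p = 0.198, 0.254 and 0.365) and in the other 3 series lists (0.0608 to 0.323). Those of 2R, 3R and the unplaced scaffolds were lost in the own list of replicate 2 (exact adjusted p = 0.475, 0.195 and 0.822), where the scaffolds held 1.66%, that of 3R also among peaks shared by any pair of replicates (0.159 to 0.24), and that of 2R among those shared by 2 and 3 (0.0601) or by 1 and 2 (0.0625). Over 13 alternatives in all, the call of 2L was lost in 12, that of 2R in 4 and that of 3R in 8. The 13 include the restriction to an IDR of 0.01 or less, which removed 0 peaks. It was the only alternative in which 2L kept its call. In the replicates' own lists chromosome 4 held 0.742% ± 0.215 (SD, n = 3). Against arm length in place of candidates, the share of chromosome 4 was no longer higher than its length gave (exact adjusted p = 0.344), and it did not pass among peaks shared by replicates 2 and 3 (0.524%, adjusted p = 0.0601) or by replicates 1 and 2 (0.424%, adjusted p = 0.208).

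The DNA replication-related element (DRE, TATCGATA), the core promoter word bound by the factor Dref, had the highest ratio of summits to flanks among the 13 fixed motifs in the conservative list. It occurred in 15.3% of the 4467 conservative summit windows of 101 bp and in 0.638% of windows centred 500 bp away (odds ratio 28.2, exact adjusted p = 1.88e-265). In the replicates' own lists it occurred in 20.1% ± 2.55 of summit windows and 0.613% ± 0.0312 of flanks (SD, n = 3). Motif 1 (GGTCACACT), the promoter word bound by M1BP, occurred in 3.36% against 0.257% (exact adjusted p = 6.65e-48), and in 3.97% ± 0.457 of the replicates' windows (SD, n = 3). Ohler motif 7 (CAKCNCTR), another core promoter element of broadly expressed genes, occurred in 15.2% against 4.03% (exact adjusted p = 6.46e-107), and in 18.1% ± 1.76 (SD, n = 3). Ohler motif 6 occurred in 0.604% against 0.123% (exact adjusted p = 6.19e-06). The word of the insulator protein CTCF (AGRTGGCG) occurred in 2.28% against 0.571% (exact adjusted p = 9.2e-17).

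Other promoter elements were not concentrated at the sites. The TATA box occurred in 1.41% of summit windows against 1.48% of flanks (exact adjusted p = 0.819) and the initiator in 19.4% against 19.9% (adjusted p = 0.5). The TCT word, the start element of ribosomal protein genes, was less frequent at summits, at 4.5% against 6.34% (exact adjusted p = 2.99e-05). The words of Zelda (exact adjusted p = 0.271), the E-box (0.284), Su(Hw) (0.153) and Pho (0.5) did not pass; their summit shares were 0.56%, 1.61%, 0.358% and 0.963%. The GAGA word, bound by Trl, passed in the conservative list (2.4% against 1.56%, exact adjusted p = 0.00149), where its log2 ratio was 0.62, but among the replicates' own lists in that of replicate 1 alone. It occurred in 3.12% of the summit windows of replicate 1, 1.19% of replicate 2 and 1.57% of replicate 3, and its log2 ratio was −0.80 in peaks shared by replicates 2 and 3 (exact adjusted p = 0.0833), 0.29 in those shared by 1 and 3 (0.45) and −0.56 in those shared by 1 and 2 (0.137). In peaks held by all 3 replicates GAGA was less frequent at summits than in flanks, at a log2 ratio of −0.96 (exact adjusted p = 0.0388). When promoter summits were set against candidate promoters, DRE stood at 19.0% against 0.376% (exact adjusted p below 2.23e-308), and GAGA no longer differed (1.99% against 2.05%, adjusted p = 0.843). Neither this comparison nor that with flanks was matched on distance to the TSS. Of the promoter summits, 79.6% lay within 100 bp of a TSS. Candidates were spread more evenly, with 2.20% to 3.27% of them in each bin of 100 bp up to 500 bp. The differences in promoter words may therefore include a difference in distance to the TSS.

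**Figure D2:**
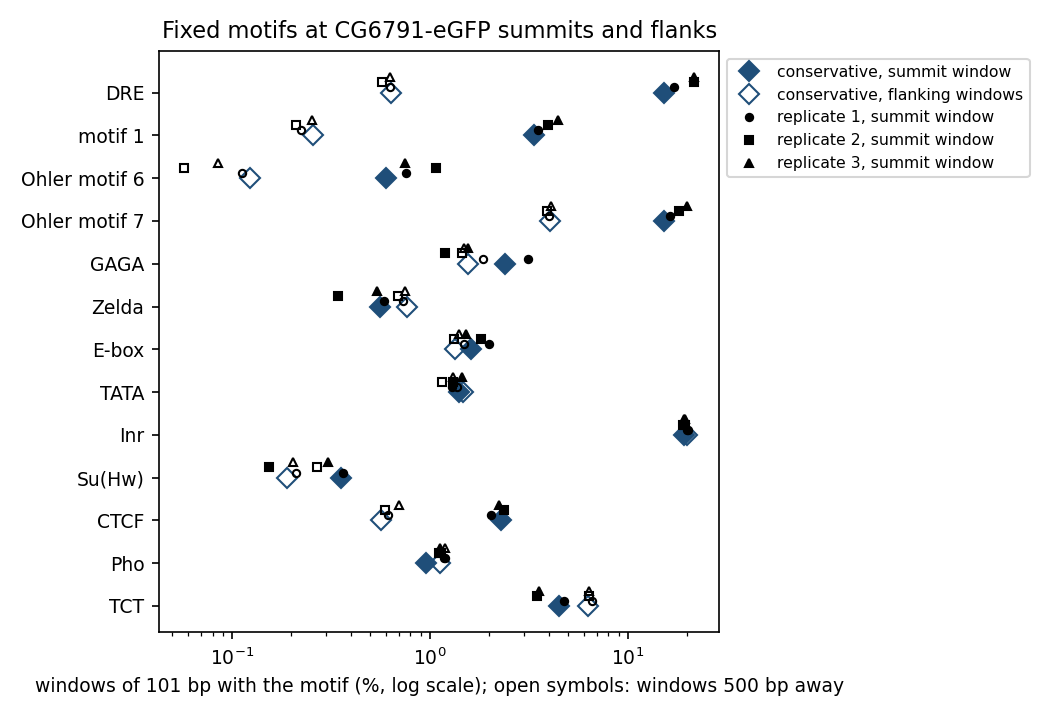
Share of 101 bp windows that hold each of 13 motifs fixed before the data were examined (horizontal axis, percent, log scale), at summits (filled symbols) and at windows 500 bp to each side (open symbols), for the conservative list (diamonds) and each replicate's own list (circles, squares and triangles). DRE stands at 15.3% of conservative summit windows and 0.638% of flanks, and GAGA stands at 3.12% against 1.87% of flanks in replicate 1 and at 1.19% against 1.46% in replicate 2.

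An unrestricted count of all 8-base words was headed by the DRE and words that overlap it. Of 31996 words tested, 1040 were more frequent and 476 less frequent at the conservative summits than in the flanks (Fisher's exact test, Benjamini-Hochberg adjusted p under 0.05). TATCGATA headed the list (685 windows, 15.3%), followed by ATCGATAG (15.3% against 0.839%, exact adjusted p = 1.12e-245). ATCGATAG came first in replicate 2's own list, in peaks shared by any pair of the replicates' own lists or held by all 3, and against candidate promoters. Of the first 20 words, 16 held CGATA on one strand. Another 3 held ATCGAT. GGTCACAC, part of motif 1, was the remaining word of these 20, in 4.39% against 0.481% of windows (exact adjusted p = 8.02e-52). CATCTCTA, a form of Ohler motif 7, occurred in 2.75% against 0.325% (exact adjusted p = 6.85e-31). CAACACTG occurred in 2.8% against 0.369% (exact adjusted p = 1.35e-29).

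Of the 15 strongest shared sites, 14 lay at promoters. The strongest conservative peak was the exception. It lay in an intron of org-1, a T-box transcription factor gene, at X, 8452211 to 8452515, 2496 bp from the nearest TSS, with a signal of 2211. Its signal also varied most among the 15 strongest shared sites, at 740 ± 396 (SD, n = 3) over the replicates' own lists. The site covered a tandem array of the unit GGTTAAAG. The next were promoters of MESK2 (2R, 21501879 to 21502175, signal 2092, replicates 718 ± 83.5), Rpn6, a proteasome lid subunit (2R, 14752212 to 14752542, 1543, 512 ± 52.6) and Capr (3L, 18673074 to 18673339, 1422, 478 ± 5.1), each as SD over n = 3. Daxx (signal 1383), milt, an adaptor for mitochondrial transport (1369), RpL32, a ribosomal protein (1329), Sumo, the ubiquitin-like modifier (1306) and Ube3a, a ubiquitin ligase (1296) followed. The remaining sites of the first 15 were the promoters of EndoGI, jagn, Pym, SMC1, a cohesin subunit, Scsalpha1 and CG2924, with signals from 1135 to 1270. All of these promoter summits lay 8 to 127 bp from a TSS. Among the 15, the summits of Sumo, Pym and Scsalpha1 had the DRE within 50 bp.

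The sites were shared out unevenly over gene groups. Of 18277 genes, 4266 (23.3%) had a conservative summit within 500 bp of a TSS, and 2413 of them (56.6%) were also bound in all 3 replicates' own lists. Among 22 gene lists fixed before the data were examined, 8 were bound more often than other genes and 5 less often (two-sided Fisher's exact test, Benjamini-Hochberg adjustment over the 22 lists). Neighbouring genes that share a summit each counted. Some sites named below lay far from the TSS of their gene. These include mRpL17 (346 bp), mRpL33 (326 bp), Hsp83 (414 bp), su(Hw) (427 bp), Ibf1 (482 bp), HP5 (381 bp), cuff (397 bp) and snoRNA:Psi18S-1275 (358 bp). Whether such sites belong to a neighbouring promoter was not tested.

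Transfer RNA genes were the most clearly bound group. A site lay at 201 of 290 (69.3%), against 22.6% of all other genes (odds ratio 7.73, exact adjusted p = 1.92e-61), and the replicates gave 65.4% ± 4.37 (SD, n = 3) against 17.7% ± 1.46. The strongest was tRNA:Glu-CTC-2-3 (3L, summit 22847758, signal 704, replicates 238 ± 67.2), then tRNA:Gly-TCC-1-2 (3R, summit 7130977, signal 649, 215 ± 95.9) and tRNA:Leu-AAG-1-3 (2R, summit 17145383, signal 641, 218 ± 83.8), each SD over n = 3. Many tRNA genes lie in clusters of near-identical copies, and reads of such copies can be hard to place. Small nuclear RNA genes did not pass (10 of 32, 31.2%, exact adjusted p = 0.384); their strongest site was at snRNA:7SKa (3R, signal 1028). Small nucleolar RNA genes, many of which lie inside introns, were bound less often (26 of 269, 9.67%, against 23.5%, exact adjusted p = 3.48e-08). The strongest of these were snoRNA:U3:54Ab, at the same site as tRNA:Leu-AAG-1-3, snoRNA:Psi18S-1275 (signal 571) and snoRNA:Psi18S-176 (signal 539). With a window of 1000 bp the snoRNA share was 23.4% (exact adjusted p = 0.347).

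Genes of the translation and protein turnover machinery were bound more often. Cytosolic ribosomal protein genes had a site at 53 of 93 (57.0%, against 27.1% of other protein-coding genes, exact adjusted p = 1.09e-08), with 46 bound in each replicate (49.5%). RpL32 (3R, signal 1329, replicates 436 ± 37.4), RpS2 (2L, 947, 326 ± 42.1) and RpS24 (2R, 661, 222 ± 9.66) were the strongest (SD, n = 3). Translation initiation factors followed with 22 of 44 (50%, exact adjusted p = 0.00398, replicates 45.5% ± 3.94), led by eIF3f1 (signal 902), eIF2gamma (891) and eIF2Balpha (809). Mitochondrial ribosomal proteins had a site at 37 of 73 (50.7%, exact adjusted p = 9.04e-05, replicates 39.7% ± 9.88), led by mRpL4 (979), mRpL17 (727) and mRpL33 (630.1). The proteasome list had 21 of 48 (43.8%, exact adjusted p = 0.0244, replicates 41.0% ± 5.24), led by Rpn6, Rpn10 (661) and Prosalpha7 (636). The mitochondrial call was lost in replicate 2's own list (28.8%, exact adjusted p = 0.119) and among peaks shared by replicates 2 and 3 (26.0%, 0.118) or 1 and 2 (27.4%, 0.0575), and the proteasome call in replicate 1's (35.4%, adjusted p = 0.105) and with a window of 1000 bp (0.0972). The initiation factor call was lost when each summit counted for its nearest TSS alone (34.1%, exact adjusted p = 0.0683).

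**Figure D3:**
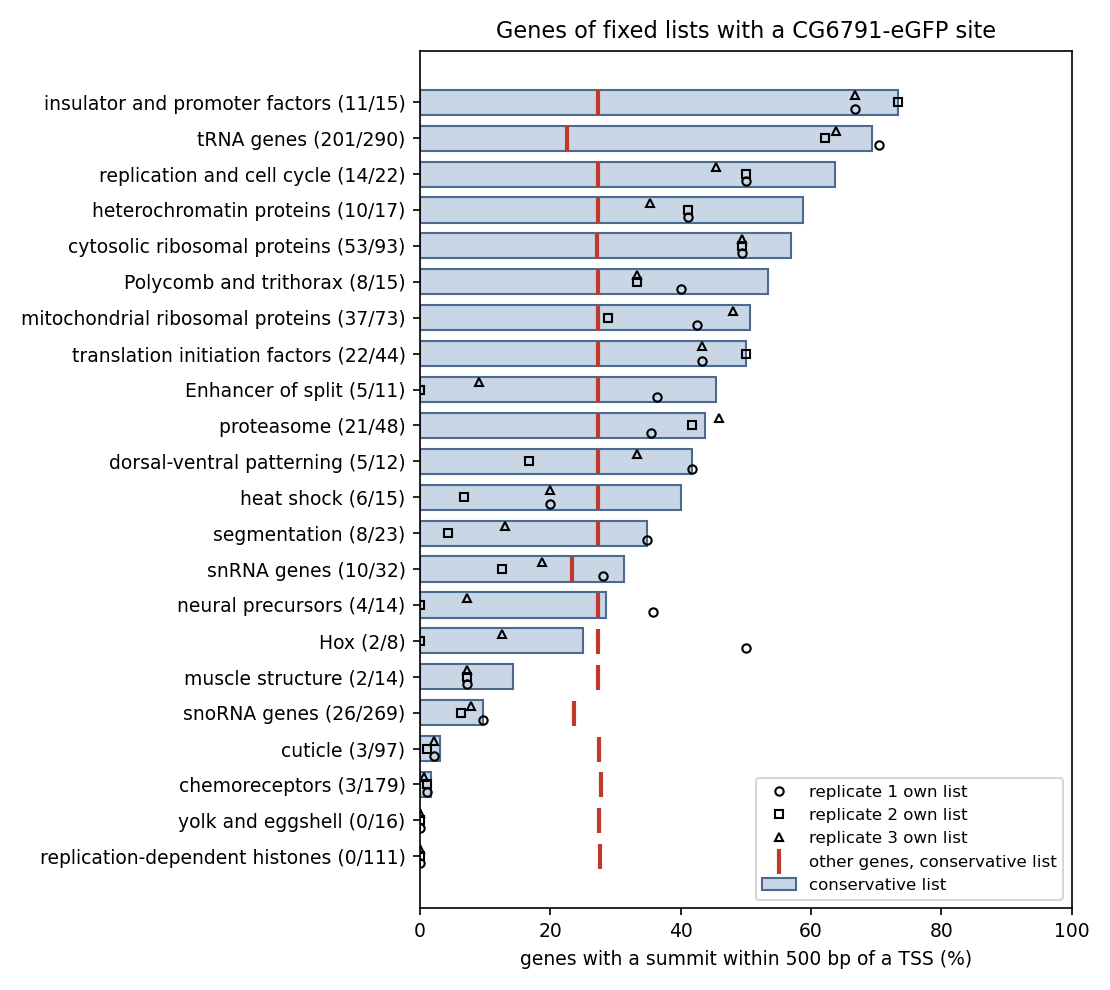
Share of the genes of each fixed list with a summit within 500 bp of a TSS (horizontal axis, percent), in the conservative list (bars, with bound and total genes beside each name) and in each replicate's own list (symbols). Red marks give the share of genes outside the list in the conservative list. These are all other genes for the tRNA, snRNA and snoRNA lists, and other protein-coding genes for the rest. Transfer RNA genes and insulator factors reach 69.3% and 73.3%, and the Hox, neural and Enhancer of split lists spread widely over the replicates.

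Genes for chromatin architecture and cell division were also bound more often. Insulator and promoter factor genes had the highest share, at 11 of 15 (73.3%, exact adjusted p = 7.55e-04, replicates 68.9% ± 3.85, n = 3). Of these, BEAF-32 (2R, signal 426), Ibf2 and Ibf1, which share one site (3R, 418), pita (344), dwg (317), Cp190 (264), mod(mdg4) (228) and ZIPIC (158) were held by all 3 replicates. Dref (168) and pzg (158) were held by replicates 2 and 3, and su(Hw) (123) by replicate 1. The sites of Ibf1 and Ibf2, Cp190 and mod(mdg4) had the DRE. Replication and cell cycle genes had 14 of 22 (63.6%, exact adjusted p = 9.73e-04, replicates 48.5% ± 2.62), led by CycB (2R, 805), Orc5 (430) and geminin (423). That call was lost among peaks shared by any pair of replicates' own lists (31.8% to 36.4%, adjusted p 0.0886 to 0.159).

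Heterochromatin protein genes had 10 of 17 (58.8%, exact adjusted p = 0.0195), a call lost in every replicate's own list. In the own lists of replicates 1, 2 and 3 the shares were 41.2%, 41.2% and 35.3% (exact adjusted p = 0.14, 0.109 and 0.394), and in peaks shared by any pair of them 23.5% to 29.4%. Su(var)3-9, a histone methyltransferase gene (3R, signal 891), lay at the same site as eIF2gamma. It was followed by row (774), Lhr (429) and HP4 (376), and these 4 were held by all 3 replicates. Hmr (170.0), HP5 (144), HP1b (129), wde (122), HP1c (101) and cuff (78.4) were held by 0 to 2 replicates, with cuff held by none. Polycomb and trithorax genes did not pass (8 of 15, 53.3%, exact adjusted p = 0.0593); Pc had the strongest site (3L, 364, replicates 132 ± 14.4). That list passed with windows of 200 bp (exact adjusted p = 0.0184) and 1000 bp (0.0379), with the nearest TSS alone (0.0109) and in the other 3 series lists (0.00615 to 0.0367).

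Genes of embryonic patterning did not pass, and differed widely between replicates. Segmentation genes had 8 of 23 (34.8%, exact adjusted p = 0.53), dorsal-ventral genes 5 of 12 (41.7%, 0.402), Hox genes 2 of 8 (25%, 1), neural precursor genes 4 of 14 (28.6%, 1) and Enhancer of split genes 5 of 11 (45.5%, 0.272). Over replicates 1, 2 and 3, Hox genes stood at 50%, 0% and 12.5% and segmentation genes at 34.8%, 4.35% and 13%. The strongest members were Mef2 (signal 310), abd-A (257), odd (169), E(spl)mbeta-HLH (156) and pros (134), and of these Mef2 alone was held by all 3 replicates. Heat shock genes (6 of 15, 40.0%, exact adjusted p = 0.357, led by Hsp83 at 311) and muscle genes (2 of 14, 14.3%, adjusted p = 0.435, led by Tm1 at 140) did not pass.

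The chemoreceptor, cuticle, yolk and eggshell, and histone lists were bound less often in the conservative list. Chemoreceptor genes had a site at 3 of 179 (1.68%, against 27.7%, exact adjusted p = 9.68e-20), namely Ir60e (signal 216), Ir60b (148) and Ir75d (79.2). Cuticle genes had 3 of 97 (3.09%, exact adjusted p = 3.04e-09), and these were Tbc1d8-9 (141), Tbp, the TATA-binding protein gene (106) and Tbca (93.1). All 3 entered the list through the symbol stem Tb and are not cuticle genes. That stem brought in 12 of the 97 genes, and 0 of the other 85 were bound. Yolk and eggshell genes had 0 of 16 (exact adjusted p = 0.0188), a call lost in every replicate's own list (adjusted p 0.0578 to 0.109) and in the peaks shared by any pair of them (0.155 to 0.173). Replication-dependent histone genes had 0 of 111 (exact adjusted p = 3.52e-15). Their cluster (2L, 21416953 to 21541681) held 2 ranked candidates in all, or 1.6 per 100 kb against 104 per 100 kb over the arms. Of these, 1 was at the passing score but absent from the conservative list. It lay 73 bp from the TSS of His3:CG31613 (signal 255.7), with 2 histone genes within 500 bp. Among genes with a candidate the list had 2 members and could not be tested (exact adjusted p = 1).

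CG6791 itself had a site at its own promoter. CG6791 (FBgn0037918) lies on the minus strand of 3R, 11585354 to 11590146. The conservative peak (11590106 to 11590284) had its summit at 11590211, 65 bp from the TSS, between CG6791 and the neighbouring gene Jupiter. Its signal was 559, with rank 222 of 4476, and the own lists gave 181, 184 and 196, a mean of 187 ± 7.72 (SD, n = 3). Replicate 1 alone had a second peak within 2000 bp, with a signal of 47.0. The labels call the flies transgenic, and a transgene can add copies of its own sequence. Whether such copies raised the signal at CG6791 was not tested, because no input library was analysed here. At w, the eye colour gene used to mark transgenes (X, 2790599 to 2796466), neither the conservative list nor any replicate's own list had a peak within 2000 bp. The 6 Hsp70 genes also had none in these lists, although 1 ranked candidate at the passing score near Hsp70Ab was absent from the conservative list.

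**Figure D4:**
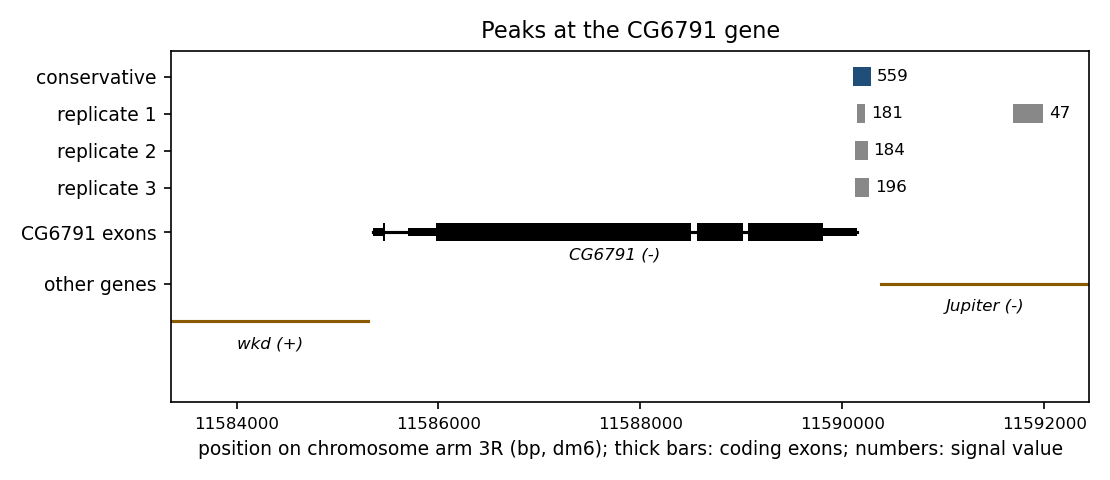
Map of CG6791 and its neighbours on arm 3R (horizontal axis, position in bp, dm6), with the peaks of the conservative list (blue) and of each replicate (grey) as bars to scale, and the signal value beside each; genes that run past an edge end there. The promoter peak of CG6791 is present in all 4 lists, with signals of 181, 184 and 196 in the replicates.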

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

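The tests in this part were chosen after the sites had been seen. One signal lay in data that the comparisons do not use. The ranked candidates behind the conservative list held 155 entries at or above its score of 830 that the conservative list lacks, 137 on the arms and 18 on unplaced scaffolds. Their median signal was 139, and 92 were at promoters. The strongest were at the promoters of osa (3R, signal 1265), Bicra (1012) and kibra (966), levels at which the conservative list has its first 50 sites. Only 2 of the 155 overlapped any thresholded list of the series. Within gaps of 20000 bp, 27 regions held 2 or more of them, 90 in all, such as 8 entries around chic, eIF4A and ifc (2L, 5977549 to 5987303) and 5 at a tRNA cluster (2R, 19725880 to 19729033). They include 8 tRNA genes with no conservative site and a site near Hsp70Ab. The named sites therefore omit some of the strongest candidates.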

How the results depend on the processing

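The alternatives with transposable elements counted as genes, the peaks held by all 3 replicates and those for motifs of intron and intergenic sites were chosen after seeing the data. Replicate overlap stayed above chance in all 7 alternatives (63.2% to 79.5%), and promoter share stayed above candidates in all 17 (66.0% to 91.3%). The planned restriction to an IDR of 0.01 or less is counted among the alternatives for promoter share and for motifs. It removed 0 peaks, so it tests nothing. DRE, motif 1 and Ohler motifs 6 and 7 kept their direction and call in all 14 alternatives. Where no cause is named below, the cause was not tested.

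Rank agreement (0.762) fell to 0.277 over ranked candidates, and was 0.702 to 0.806 without one replicate. The share held by all replicates (42.8%) was 31.5% with reciprocal 50% overlap and 40.5% with summits within 100 bp. The intron and intergenic share (18.7%) was 11.6% in replicate 2, 12.6% in replicate 3, 15% and 14.8% in the lists of replicates 1 and 2 and of 2 and 3, 24.7% in the pooled list, 9.52% in the peaks above the median signal, 7.83% in peaks held by all 3 replicates, 23.7% with a TSS window of 200 bp, 14.2% with 1000 bp and 8.34% to 10.1% without one replicate. The chromosome classes past the threshold (6, namely 5 arms and the unplaced scaffolds) were 2 in replicate 2, 3 in the list of replicates 1 and 2, 3 in peaks held by all 3 replicates, 2 against arm length, which has no class for unplaced scaffolds, and 2 to 4 without one replicate; chromosome 4 against arm length held 0.784% (exact adjusted p = 0.344).

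Motifs less frequent at summits numbered 1, and 2 in the list of replicates 2 and 3, the pooled list and the peaks held by all 3 replicates. The log2 ratio of GAGA turned from 0.62 to −0.28 in replicate 2, −0.0067 in the list of replicates 2 and 3, −0.96 in peaks held by all 3 replicates, where it passed as lower (exact adjusted p = 0.0388), −0.039 against candidate promoters and −0.80 to 0.29 without one replicate (−0.56 without replicate 3). The Su(Hw) word, higher at intron and intergenic than at promoter summits (1.08% against 0.146%), was in 0% of the former in peaks held by all 3 replicates (exact adjusted p = 1) and 0% to 2.1% without one replicate. The 8-base words less frequent at summits (476) were 192 in peaks held by all 3 replicates and 244 to 274 without one replicate, which leaves fewer windows, and 873 with 7-base words. Gene lists bound more often (8) were 4 in the peaks above the median signal, 5 in peaks held by all 3 replicates and 5 to 6 without one replicate. Near CG6791, replicate 1 had 2 peaks. Of 1537 values of single motifs, arms, lists and named sites under an alternative, 1326 stayed on their side of the threshold, 188 lost the call, 14 gained it and 9 that had passed turned. The 1326 are no measure of robustness. They include the 71 named sites under 12 alternatives each. Many of these sites were held by all 3 replicates, so their presence in each own list was fixed in advance. The restriction to an IDR of 0.01 or less removed 0 peaks and left every value as it was. Changes of direction among values that had not passed were not counted. Read depth is unknown, so what it limits could not be judged.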

Other observations

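The tests in this part were chosen after the sites had been seen, and those of the DRE and of the U genes for tRNA sites, of the words from other arms and of the variation at org-1 only after the results they measure. Sites outside promoters carried some words in other shares than promoter sites. Among 837 intron and intergenic summits of the conservative list, the CTCF word occurred in 5.85%, against 1.26% of 3422 promoter summits (Fisher's exact test, adjusted p = 1.76e-12 over 13 motifs), and DRE in 3.94% against 19.0% (exact adjusted p = 7.93e-32). Ohler motif 7 occurred in 5.85% against 17.9% (exact adjusted p = 2.49e-20). The DRE was still more frequent at these 837 summits than in their flanks (3.94% against 0.597%, Fisher's exact test, adjusted p = 2.42e-06 over 8-base words). All 3 replicates held 13.8% of the intron and 23.6% of the intergenic sites, against 51.1% of the promoter sites. Among the peaks held by all 3, CTCF stood at 7.33% of 150 against 1.43% of 1749 (exact adjusted p = 3.6e-04) and DRE at 11.3% against 28.7% (exact adjusted p = 1.7e-05). Without one replicate, CTCF was at 4.74% to 7.43% and DRE at 7.56% to 9.14% of intron and intergenic summits, and both calls held. GAGA (4.3% against 1.99%, exact adjusted p = 6.64e-04) and Su(Hw) (1.08% against 0.146%, adjusted p = 7.02e-04) passed in the conservative list and in the own lists of replicates 1 and 3, but not in that of replicate 2 (exact adjusted p = 0.918 and 0.159). They also did not pass among peaks held by all 3 (exact adjusted p = 0.566 and 1), without replicate 1 (0.848 and 1) or without replicate 3 (0.595 and 0.113). Over 10 equal classes of signal, the DRE share was 1.56% in the weakest and 30.8% in the strongest, and the promoter share 62.5% and 97.3%. Among other small RNA genes, chosen after their values were seen and not tested as a group, the U6 copies (snRNA:U6:96Ac, signal 440, snRNA:U6:96Ab, 235, and snRNA:U6:96Aa, 171), snRNA:7SKa (1028) and RNaseMRP:RNA (328) had sites. Both 7SL RNA genes, snRNA:7SKb, snRNA:U6atac and RNaseP:RNA had none.

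Of 68 genes in the 5 patterning lists, 26 were bound in replicate 1, 3 in replicate 2 and 10 in replicate 3. With each list limited to its 2643 strongest peaks, 16, 3 and 10 were bound.

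The first pattern is the share of tRNA genes with a site (69.3%, against 22.6% of other genes). Neighbouring protein-coding promoters do not account for it, since 66.8% of the 211 tRNA genes over 1000 bp from such a TSS were bound (95% Wilson interval 60.2 to 72.8). Reads shared between identical copies were tested less cleanly. Of the 52 tRNA genes whose sequence occurs once, 55.8% were bound (42.3 to 68.4). Of the 39 of these also over 1000 bp from a protein-coding TSS, 51.3% were bound (36.2 to 66.1). A summit within 500 bp counted even when it lay at another tRNA gene, and the 290 tRNA genes formed 174 groups within 1000 bp of each other. Flanks of near-identical copies may also share reads, so shared reads are not excluded as the cause. The DRE was absent there, at 0% of 163 tRNA summits against 20.4% of protein-coding promoter summits (Fisher's exact test, p = 3.16e-16). Of 21 U1, U2, U4 and U5 genes, 28.6% were bound (13.8 to 50). Whether strong transcription in general accounts for the tRNA sites cannot be told from that share, because no transcription level was measured. Recovery of polymerase III genes in any precipitate stays open, because no mock precipitate was analysed here, and no biological explanation was tested.

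The second pattern is a set of sites in INE-1, a short and abundant transposable element. The word ATCAGATACC lay within 50 bp of 59 conservative summits, 32 of them in annotated INE-1 copies and 40 in introns or intergenic DNA, with 22 held by all 3 replicates; the strongest was at X, 15841448 to 15841698 (signal 846). Summits were not spread evenly over repeat families. They lay in 0.418% of 1674 copies of other families of 50 or more copies, against 2.28% of 2235 INE-1 copies (Fisher's exact test, p = 6.07e-07). The other families had longer copies, with median lengths of 186 to 8990.5 bp against 146 bp for INE-1. How reads of repeats were placed is not given in the sources used here, so misplaced reads of repeats in general are not excluded. Because the word was found in these same sites, the leading word of the other arms (CAGATACC) was tested on 3L and 3R. Among INE-1 copies of 200 bp or more there, 1 of 150 without it (0.667%) held a summit, against 6 of 83 with it (7.23%, exact p = 0.009). Length was not matched. Over all arms, such copies with ATCAGATACC had a median length of 409.5 bp, against 342 bp without it. Of these copies, 18 of 278 with that word and 3 of 633 without it held a summit, whereas 51 INE-1 copies of any length did. The limit of 200 bp therefore left out most INE-1 copies with a summit. The difference on 3L and 3R argues only weakly against misplaced reads of any INE-1 copy, because it rests on few copies of the same repeat family. Outside annotated elements on 3L and 3R, 0.6004% of 1499 occurrences of CAGATACC lay at a summit, against 0.437% of 24734 occurrences of 20 rearranged words (exact p = 0.318). Recognition of the word itself therefore cannot be told from these data, misplaced reads among the copies that share it stay open, and no biological explanation was tested.

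The third pattern is the strongest site, in an intron of org-1, over 7 units of GGTTAAAG (X, 8452314 to 8452405). Recognition of the unit cannot be told from these data, because 0 other arrays of 4 or more units within 150 bp exist in the reference arms to overlap a peak. Single units overlapped a peak at 39 of 3722 places (1.05%). No share expected by chance was computed, so this does not show binding of single units. More copies of the array in the flies than in the reference also stay open, because no input library was analysed here. The coefficient of variation of its signal over replicates was 53.6%, against 1.07% to 32.8% at the other 14 sites, with 1169, 388 and 663 in replicates 1, 2 and 3 against medians of 429, 474 and 413 at those sites, which excludes neither explanation, and no biological explanation was tested.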
